A study of Mus musculus with 31 samples.

How the data were processed

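RNA-seq was run on 31 mouse libraries. Per the labels' protocols, cells were lysed in Trizol, total RNA was purified on RNeasy columns with DNase treatment, and libraries were made with the TruSeq RNA Sample Prep Kit v2. The strand setting is not stated, so antisense and overlapping genes cannot be told apart. The authors deposited a table of expected counts per gene and a table of TPM (transcript abundance scaled to the same total in every library). Per the submitters' processing notes, reads were handled with CASAVA 1.8.2, RSEM 1.2.3 and Bowtie 0.12.9 on build mm10. RSEM's expected counts are estimates that divide reads fitting several transcripts among them, so genes with near-identical copies (the globin, stefin, Psg and Hox families, and the ectopic and endogenous transcripts of the 6 factors) are uncertain. The deposited TPM were renormalised per the file name, in a way that no source describes. The header of the TPM table holds 1 name more than its rows have cells, and the columns were assigned by header name and order after the extra name was left out. As a check, the pattern of detected genes was closest to that of the library's own count column in 31 of 31 cases. The table holds 20314 genes, all under the symbols given there. Gene positions come from the GENCODE annotation of GRCm38.

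Samples were grouped by the labels into ES cells (n = 3), Kdr-positive mesoderm (n = 3), eHB lines (n = 5), endothelial cultures of day 3 (n = 5), blood cultures of day 2 (n = 5) and day 3 (n = 5), fetal HSCs (n = 1), yolk sac endothelium (n = 2) and embryo endothelium (n = 2). The total of expected counts was 9424412 to 26651901 in day 3 blood, 13236697 to 27084974 in day 2 blood and 22844070 to 39860050 in eHB. It was 29990385 to 48340524 in endothelial cultures, 21336054 to 23954955 in ES cells, 23398047 to 32791629 in mesoderm, 24221267 to 26220764 in yolk sac, 23548227 to 30400302 in embryo endothelium, and 79497758 in HSCs. No pair of libraries within a group was a duplicate: over 48 pairs the mean chi-square per gene was 4.16 to 568, for genes with a summed count of 50 or more.

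Each of 10 comparisons was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust) on the expected counts rounded to whole numbers. TMM normalisation and filterByExpr were used, and only the groups compared entered a fit. P-values were adjusted by the Benjamini-Hochberg method and 0.05 was the threshold. The standard error of a log2 fold change is the size of the coefficient without shrinkage divided by the square root of F. Levels are deposited TPM as mean ± SD over libraries. A gene with no count in a group is given as a fold of at least the ratio to a floor of 3 counts over the group, a limit that covers counting error only. The 32 gene lists were tested with camera of limma 3.58.1 (preset correlation 0.01, lists with 3 or more tested members, adjusted over the lists of a comparison). An estimated correlation and fry, which asks whether a list's genes move on balance one way, were run beside it. Camera called 82 lists over the 10 comparisons. With an estimated correlation 8 of these calls held: the pluripotency, primitive streak, lateral mesoderm and smooth muscle lists in mesoderm against ES cells, and the pluripotency, primitive streak, lateral mesoderm and Wnt target lists in eHB against mesoderm. Members of a list were counted over all genes tested and adjusted over the list alone. HSCs were compared with day 3 blood by differences of log2(TPM + 1) without a test, and list medians were set among 10000 random lists matched on mean expression in 20 bins. Similarity to controls used genes with at least 1 TPM in at least 2 libraries. Origin was compared between stages in a fit with an interaction term, without and with the line as a block.

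Genes were named by a rule. Part a took the sorting markers Kdr, Cdh5, Pecam1 and Ptprc and the 6 factors. Part b took the 6 largest positive and 6 largest negative log2 fold changes among called genes with a mean of 20 TPM or more in the higher group and no overlap between groups, leaving out predicted genes, clone-named genes and small RNA genes. Part c took up to 3 called members of each called list in its direction and 1 in the opposite direction. For HSCs, the 6 highest and 6 lowest differences outside the range of blood at 20 TPM or more were taken. The text gives fewer, in the order of the rule, and some items that the rule names are not reported here. The groups, tests, lists, naming rule and alternatives were chosen before the data were examined, with these exceptions. The 6 ectopic transcripts, the fits with an interaction, the tests of origin in blood cultures and the tests of BMP targets, Hox genes, Gata2 and scaling in the closing part were chosen after their results were seen. The epithelial list was written after the data were examined and before its values were seen. The alternatives added later were the block and the estimated correlation for the interaction, and the removal of 14 gene entries (ectopic transcripts, globins and Lars2).

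The lines pair the cultures, since per the labels the eHB, endothelial and blood libraries of a line, and the ES and mesoderm libraries of a line, come from the same cell line. Deviations from the group means correlated within a line at 0.311 to 0.491 for eHB and endothelial cultures, 0.257 to 0.43 for eHB and day 2 blood, 0.245 to 0.656 for both blood stages, 0.133 to 0.323 for endothelial cultures and day 3 blood, and -0.058 to 0.046 for ES cells and mesoderm. The line as a block was an alternative.

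The alternatives were DESeq2 size factors, no filter on low counts, the Wald test of DESeq2 1.42.0, a single fit of all 31 libraries, glmTreat against a 2-fold change, limma-trend on log2(TPM + 1) for genes with a mean of 1 TPM or more, a replicate block, each primary endothelium alone, fetal liver lines alone, a pseudocount of 0.1, other gene sets and Pearson correlation for the similarities, and leaving out each library in turn. The fit was tested on simulated counts with 200 genes changed, for each comparison. It recovered 5.97% (day 3 against day 2 blood, 11947 genes) to 65.7% (mesoderm against ES cells, 13385 genes) of 2-fold changes. For 4-fold changes the range was 53.7% (origin in endothelial cultures, 12662 genes) to 97% (mesoderm against ES cells). False calls numbered 2 to 18 per comparison. As a share of all calls, they were highest for origin in eHB (15 of 111) and in endothelial cultures (12 of 98). Next came yolk sac against embryo (18 of 183) and mesoderm against ES cells (13 of 184). Day 3 blood against endothelial cultures (8 of 126) and day 2 blood against eHB (6 of 114) followed. All of these shares exceeded the threshold on adjusted p. The lowest share was 2 of 132, for endothelial cultures against primary endothelium. With 200 genes changed, normalisation was not tested where most genes move. In mesoderm against ES cells the real data called 79.1% of genes. Sequence-level questions were not analysed here, since no reads were used.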

Results

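Messenger RNA levels were measured by RNA-seq in 31 mouse libraries made from total RNA of cultured or freshly isolated cells. The study concerns expandable hemangioblasts (eHBs). A hemangioblast is a progenitor that can give rise to blood and to endothelium, the cell layer that lines vessels. The 5 eHB lines were kept in medium with 2 µg/mL doxycycline, a drug commonly used to switch on inducible transgenes. Lines RB3.6.5 and RB4.6.9 came from embryonic stem (ES) cells, M5 from embryonic fibroblasts, and FL4 and FL10 from fetal liver. Each line was also cultured for 3 days without doxycycline in a medium with VEGF, BMP4 and FGF2 (endothelial cultures, n = 5). That medium also held the TGF-beta receptor inhibitor SB431542 and a cyclic AMP analogue. Blood cultures were kept with SCF, IL-3, Flt3L and the Wnt pathway activator CHIR99021 at 1.5% oxygen. They were sorted for VE-cadherin without CD45 on day 2 (n = 5), and for VE-cadherin with CD45 on day 3 (n = 5). The controls were 3 ES lines, Kdr-positive mesoderm made from the same 3 ES lines, 1 library of E14.5 hematopoietic stem cells (HSCs), and endothelium sorted from yolk sac (n = 2) and embryo (n = 2) at E11.5 (E, embryonic day). The libraries held 9424412 to 79497758 counts. Blood day 3 of line RB3.6.5 was the shallowest and the HSC library the deepest, and the eHB libraries held 22844070 to 39860050. The eHB, endothelial and blood replicates are separate lines. Nothing in the labels says whether the replicates of yolk sac or embryo came from separate animals, so p-values there may measure technical spread alone. TPM levels are means ± SD, and log2 fold changes carry their standard error (SE).

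The tables list, beside the endogenous genes, an ectopic transcript for transcription regulators, among them Gata2, Lmo2, Mycn, Sox17 and Tal1, and these rows were added to the genes followed after they were seen in the tables. In eHB cells these 5 ectopic transcripts were abundant: 14.3 to 1460 TPM for Gata2, 737 to 5630 for Lmo2, 1140 to 3770 for Mycn, 754 to 1220 for Sox17 and 1300 to 4230 for Tal1 over the 5 lines. In the doxycycline-free progeny no library exceeded 18.3 TPM for Gata2, 146 for Lmo2, 28.6 for Mycn, 22.3 for Sox17 and 140 for Tal1. In the controls (ES cells, mesoderm, primary endothelium and HSCs) the highest of these was 4.67 TPM, for Lmo2. The endothelial cultures stood below eHB for each of the 5 ectopic rows, from Tal1 (log2 fold change -5.71 ± 0.74 SE, adjusted p = 5.99e-05) to Mycn (-8.18 ± 0.68, adjusted p = 2.91e-06). Among the endogenous rows of the eHB lines, Tal1 (98.7 to 162 TPM) and Gata2 (74.8 to 129 TPM) were high in all 5. Endogenous Lmo2 ranged from 2.47 to 58.6 TPM, and Mycn and Sox17 stayed at or below 19.9 and 3.64 TPM. The ectopic and endogenous transcripts of a factor share their coding sequence, so the split of reads between these rows is uncertain.

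**Figure D1:**
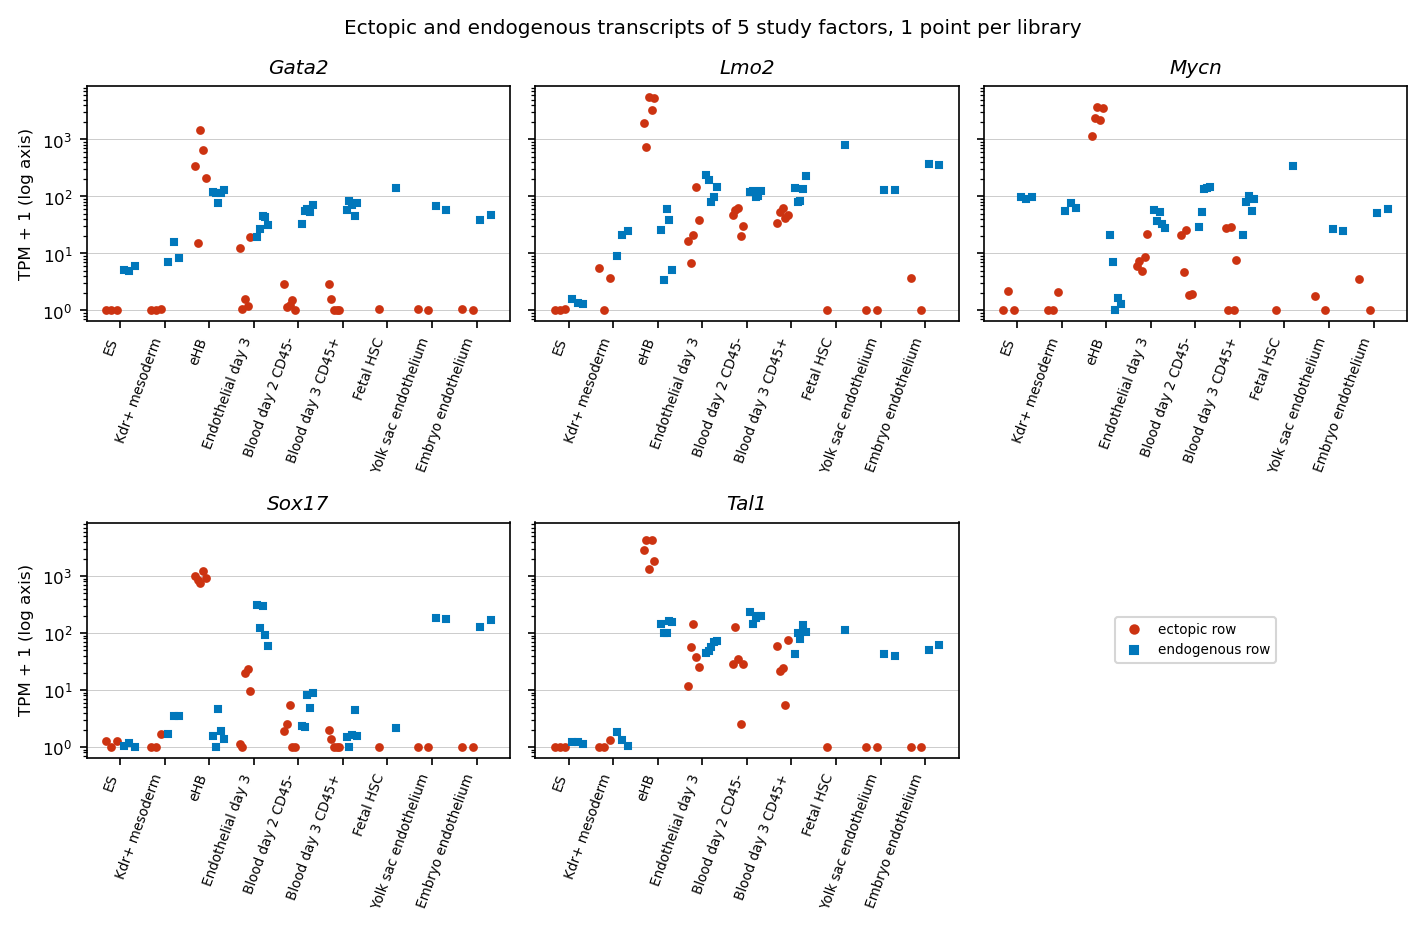
Ectopic (red circles) and endogenous (blue squares) transcript levels of 5 factors, in TPM + 1 on a log axis, with 1 point per library in each of the 9 sample groups. Ectopic levels in eHB lie above those of every other group for Lmo2, Mycn, Sox17 and Tal1, whereas ectopic Gata2 spans 14.3 to 1460 TPM in eHB and reaches 18.3 TPM in the progeny.

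On the reference genome (GRCm38, GENCODE annotation), the sorting markers are Kdr (ENSMUSG00000062960, chromosome 5, 75932827 to 75978458), Cdh5, which encodes VE-cadherin (ENSMUSG00000031871, chromosome 8, 104101625 to 104144511), Pecam1 (ENSMUSG00000020717, chromosome 11, 106654217 to 106750628) and Ptprc, which encodes CD45 (ENSMUSG00000026395, chromosome 1, 138062861 to 138175708). Gata2 (ENSMUSG00000015053) lies on chromosome 6 at 88193891 to 88207032 and Lmo2 (ENSMUSG00000032698) on chromosome 2 at 103957986 to 103981878. Mycn (ENSMUSG00000037169) lies on chromosome 12 at 12936093 to 12941914, Sox17 (ENSMUSG00000025902) on chromosome 1 at 4490931 to 4497354 and Tal1 (ENSMUSG00000028717) on chromosome 4 at 115056426 to 115071755.

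The comparison of mesoderm with ES cells asked what separates the Kdr-sorted intermediate from its source. Pluripotency transcripts were lower in mesoderm, and transcripts of the primitive streak and of lateral mesoderm were higher. Kdr, a VEGF receptor, was at 79.9 ± 22.5 TPM in mesoderm and 0.109 ± 0.0477 TPM in ES cells (log2 fold change 9.87 ± 0.34 SE, adjusted p = 6.2e-08, n = 3 and 3). In the pluripotency list 19 of 21 members fell and 2 rose (camera adjusted p = 3.94e-29, adjusted p = 0.0197 with an estimated correlation). Tcl1 (at least 2350-fold lower) and Dppa3 (at least 921-fold lower) were at 0 in all mesoderm libraries, while Lin28a, an RNA-binding protein also active in early differentiation, rose (2.09 ± 0.13, adjusted p = 7.73e-07). In the primitive streak list 12 of 14 rose and 1 fell (camera adjusted p = 6.09e-06, adjusted p = 0.0487 with an estimated correlation). Lhx1 went from 0.0293 ± 0.00635 to 28.97 ± 11.86 TPM, Msgn1 was at least 119-fold higher, and Cdx1 fell (-1.99 ± 0.34, adjusted p = 0.000558). In the lateral mesoderm list 14 of 15 rose (camera adjusted p = 3.87e-14, adjusted p = 0.0197 with an estimated correlation), among them Hand1 (10.57 ± 1.08, adjusted p = 4.72e-05). Foxf1 was at 51.6 ± 41.7 TPM in mesoderm and 0.0143 ± 0.0248 TPM in ES cells.

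Genes of smooth muscle and mural cells also rose in mesoderm (8 of 10, camera adjusted p = 4.63e-07, adjusted p = 0.0479 with an estimated correlation), with Cnn1 at least 532-fold higher. BMP target genes rose in 6 of 9 cases and fell in 1 (camera adjusted p = 0.000621, adjusted p = 0.1 with an estimated correlation), led by Id1 (6.80 ± 0.18, adjusted p = 7.75e-09) and Id3 (5.49 ± 0.22, adjusted p = 1.03e-07), with Id4 lower (-3.74 ± 0.43, adjusted p = 4.89e-05). FGF and ERK targets rose in 14 of 18 cases and fell in 3 (camera adjusted p = 0.000745, adjusted p = 0.359 with an estimated correlation). Per the labels, the ES medium contained PD0325901, which blocks ERK signalling, and the mesoderm medium did not. The mesoderm medium contained FGF2 and BMP4, and the ES medium did not. For the BMP, FGF and ERK targets, medium and cell stage therefore cannot be told apart. Wnt targets rose in 9 of 12 and fell in 1 (camera adjusted p = 0.0124, adjusted p = 0.533 with an estimated correlation), and imprinted genes rose in 11 of 14 and fell in 1 (camera adjusted p = 0.000313, adjusted p = 0.142 with an estimated correlation). Nkd1 (6.51 ± 0.46), Egr1 (6.53 ± 0.27) and Peg10 (6.91 ± 0.38) were among the members that rose (largest adjusted p = 5.8e-06). Adjusted over the list alone, the counts were the same for all 8 of these lists. Outside the lists, Cyp26a1, which degrades retinoic acid, reached 222 ± 81.4 TPM in mesoderm against 0.018 ± 0.0312 TPM in ES cells, Wnt2 was at least 726-fold higher, and the cytokine gene Osm was at least 1150-fold lower. Of 13539 genes tested, 5295 were higher and 5421 lower in mesoderm, and a test against a 2-fold change (glmTreat) left 2253 and 2781. By limma on log2 TPM the split was 3556 and 6039.

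The eHB lines were set against Kdr-positive mesoderm, the control stage closest to a hemangioblast. Transcripts of endothelial and hemogenic genes were higher in eHB, and those of the streak, lateral mesoderm and pluripotency were lower. The endogenous row of Tal1 rose to 131.7 ± 30.04 TPM from 0.376 ± 0.397 TPM (8.17 ± 0.82, adjusted p = 0.000212, n = 5 and 3), and that of Gata2 rose to 109.5 ± 20.7 TPM from 9.56 ± 4.85 TPM (3.23 ± 0.31, adjusted p = 0.000168). Ectopic Tal1 was at 1300 to 4230 TPM in eHB, so for Tal1 shared reads and endogenous transcription cannot be told apart. Kdr was at 26.4 ± 21.6 TPM in eHB and 79.9 ± 22.5 TPM in mesoderm, which did not pass the test (adjusted p = 0.104). Of the hemogenic factor list, 9 of 14 rose and 2 fell (camera adjusted p = 0.00285, adjusted p = 0.462 with an estimated correlation), and 11 rose when adjusted over the list alone. Ikzf1, a regulator of lymphoid development, rose (8.82 ± 1.26, adjusted p = 0.000966), Erg was at 13.2 ± 12.3 TPM against 0.0133 ± 0.0115 TPM (adjusted p = 0.0548 by limma on log2 TPM), and Etv2, a master regulator of the earliest endothelium, fell (-5.94 ± 0.51, adjusted p = 0.000102). Of the pan-endothelial list 11 of 18 rose and 3 fell (camera adjusted p = 0.0336, adjusted p = 0.739 with an estimated correlation). Cdh5 rose (8.36 ± 1.97, adjusted p = 0.00914), Tie1 rose (10.52 ± 1.84, adjusted p = 0.00239) although line RB4.6.9 held only 0.959 TPM of it, and Eng, a TGF-beta co-receptor, fell (-4.51 ± 0.62, adjusted p = 0.000841). That list's call ended without eHB line RB3.6.5 (adjusted p = 0.0645) or M5 (0.0642), and without mesoderm RB2 (0.0676), RB3 (0.107) or RB4 (0.0727).

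The primitive streak list was lower in eHB for 12 of 14 members (camera adjusted p = 2.06e-15, adjusted p = 0.00339 with an estimated correlation). The lateral mesoderm list was lower for 10 of 16 (camera adjusted p = 3.51e-08, adjusted p = 0.0248 with an estimated correlation) and the pluripotency list for 8 of 13 (camera adjusted p = 2.48e-07, adjusted p = 0.0248 with an estimated correlation). Mixl1 fell from 325.6 ± 113.5 to 0.0364 ± 0.0381 TPM (-13.35 ± 0.50, adjusted p = 3.18e-06), and Pou5f1, which encodes Oct4, fell from 97.9 ± 29.9 to 0.0744 ± 0.0964 TPM (-10.43 ± 0.64, adjusted p = 2.9e-05). Tdgf1 and Hand1, at 347.7 ± 121 and 255.6 ± 229.7 TPM in mesoderm, were at 0.0148 ± 0.0206 and 0.0148 ± 0.0331 TPM in eHB. Wnt targets fell in 8 of 12 cases (camera adjusted p = 1e-07, adjusted p = 0.0161 with an estimated correlation), including Sp5 (-11.85 ± 0.58, adjusted p = 9.79e-06). The mesoderm medium contained the Wnt pathway activator CHIR99021 and the eHB media did not. Smooth muscle genes fell in 4 of 12 cases and rose in 1 (camera adjusted p = 0.00192, adjusted p = 0.0821 with an estimated correlation), with Tagln lower (-8.41 ± 0.39, adjusted p = 9.22e-06). Hox genes fell in 11 of 22 cases and rose in 2 (camera adjusted p = 0.00192, adjusted p = 0.361 with an estimated correlation), Hoxb1 by at least 318-fold. Except for the hemogenic factors, counts adjusted over the list alone equalled those over all genes. Lim2, known from the eye lens, was at least 991-fold higher in eHB. Of 13282 genes tested, 3117 were higher and 3069 lower, against 827 and 1087 in the test against a 2-fold change and 4527 and 1695 by limma on log2 TPM.

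The endothelial cultures were compared with the eHB lines they came from. Doxycycline was withdrawn from all 5 lines. Lines M5, FL4 and FL10 also gained VEGF, BMP4, SB431542 and the cyclic AMP analogue, which RB3.6.5 and RB4.6.9 already had as eHB. Medium and cell stage therefore cannot be told apart. Most members of the pan-endothelial, arterial and venous and lymphatic lists rose, and cell cycle genes fell. Cdh5 rose to 2890 ± 213 TPM (6.26 ± 1.17, adjusted p = 0.000773, n = 5 and 5), Pecam1 to 1622 ± 286 TPM from 34.1 ± 33.9 TPM (5.58 ± 1.12, adjusted p = 0.00119) and Kdr to 685 ± 102 TPM from 26.4 ± 21.6 TPM (4.73 ± 0.82, adjusted p = 0.000451). Of the pan-endothelial list 23 of 24 rose (camera adjusted p = 3.4e-07, adjusted p = 0.226 with an estimated correlation). Emcn was at least 1700-fold higher, and Robo4, a receptor of endothelial cells, rose to 406 ± 68.1 TPM (12.89 ± 0.57, adjusted p = 1.24e-07). Of the arterial list 9 of 14 rose and 1 fell (camera adjusted p = 0.00126, adjusted p = 0.226 with an estimated correlation), with the Notch ligand Dll4 higher (12.03 ± 0.57, adjusted p = 1.59e-07) and another Notch ligand, Jag2, lower (-3.08 ± 0.61, adjusted p = 0.00111). Of the venous and lymphatic list 7 of 10 rose (camera adjusted p = 0.00926, adjusted p = 0.226 with an estimated correlation), a call that ended with the line as a block (adjusted p = 0.082). Nr2f2 (1.37, adjusted p = 0.43), Prox1 (-0.361, adjusted p = 0.636) and Reln (-1.85, adjusted p = 0.107) of that list did not pass the test. Lyve1, a hyaluronan receptor of lymphatic and early embryonic endothelium, reached 1992 ± 535 TPM from 0.059 ± 0.103 TPM (15.04 ± 0.79, adjusted p = 2.45e-07), and Stab2 rose as well (13.28 ± 0.78, adjusted p = 4.05e-07). Endogenous Sox17 rose (7.31 ± 1.06, adjusted p = 0.000134) and Lmo2 rose (2.60 ± 0.80, adjusted p = 0.014), while Gata2 (-1.73 ± 0.24, adjusted p = 0.000112) and Tal1 (-1.15 ± 0.19, adjusted p = 0.000364) fell. For Tal1, whose ectopic row fell as well, shared reads and endogenous transcription cannot be told apart.

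The proliferation list fell in 19 of 20 cases (camera adjusted p = 4.83e-12, adjusted p = 0.226 with an estimated correlation). Ccnb1, the mitotic cyclin B1, went from 251 ± 30.9 to 10.3 ± 5.65 TPM (-4.59 ± 0.35, adjusted p = 1.83e-06) and Rrm2, needed to make DNA precursors, from 411 ± 71.7 to 17.68 ± 8.203 TPM (-4.51 ± 0.31, adjusted p = 9.72e-07). The megakaryocyte list rose in 8 of 10 cases (camera adjusted p = 0.0494, adjusted p = 0.729 with an estimated correlation), and in 9 when adjusted over the list alone, a call that ended with DESeq2 size factors (adjusted p = 0.0636). Its leading members were Clec1b (at least 528-fold higher) and Thbs1 (8.79 ± 0.72, adjusted p = 2.59e-06), and Thbs1 is also made by endothelial cells. The erythroid list was not called (camera adjusted p = 0.956), but globin and erythroid transcripts, summed after their values were seen, reached 2280 TPM in the M5 culture against 3.01 to 156 TPM in the other 4. Without that culture the megakaryocyte call held. For the other 4 lists the count adjusted over the list alone did not differ. Emp1 was at least 23800-fold and Psg22 at least 9480-fold higher, and Lim2 was at least 2060-fold lower. Of 12579 genes tested, 4320 were higher and 4483 lower in the endothelial cultures. The test against a 2-fold change left 2203 and 2114.

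Blood cultures of day 2, sorted as CD45-negative, were compared with the eHB lines. Their medium differed from the eHB media as well, so medium and cell stage cannot be told apart. Genes of red cells, megakaryocytes, leukocytes and myeloid cells were all higher, in cells whose sort excluded surface CD45. Embryonic beta-globin Hbb-bh1 averaged 13420 TPM with a SD of 14950 over the 5 cultures, against 0.217 ± 0.286 TPM in eHB (16.94 ± 1.77, adjusted p = 0.000109). Globin levels differed widely between lines, and line M5 held 3530 TPM of Hbb-bt against 132 to 507 TPM in the other 4. Of the erythroid list 19 of 20 rose (camera adjusted p = 7.05e-06, adjusted p = 0.472 with an estimated correlation). All 12 tested genes of the megakaryocyte list rose (camera adjusted p = 4.98e-09, adjusted p = 0.327 with an estimated correlation), with Treml1 at 199 ± 249.5 TPM against 0.0088 ± 0.0197 TPM. Of the leukocyte list 16 of 18 rose (camera adjusted p = 2.58e-15, adjusted p = 0.137 with an estimated correlation), including Plek, an actin regulator of platelets and leukocytes (11.97 ± 0.59, adjusted p = 4.03e-06). All 11 tested myeloid genes rose (camera adjusted p = 5.62e-08, adjusted p = 0.292 with an estimated correlation), such as Csf2rb, a shared cytokine receptor chain (9.03 ± 1.13, adjusted p = 0.000235).

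Of the hemogenic factor list 9 of 15 rose in day 2 blood (camera adjusted p = 0.000711, adjusted p = 0.327 with an estimated correlation), among them Spi1, which encodes PU.1 (8.62 ± 1.03, adjusted p = 0.00019). Of the stem and progenitor list 10 of 15 rose and 1 fell (camera adjusted p = 0.00029, adjusted p = 0.234 with an estimated correlation), and of the pan-endothelial list 8 of 20 rose (camera adjusted p = 0.0161, adjusted p = 0.536 with an estimated correlation), 6 when adjusted over the list alone. Cd34, carried by both lists, rose (10.31 ± 1.42, adjusted p = 0.000361). Line RB4.6.9 stood apart in Robo4 of the pan-endothelial list, with 32.1 TPM against 0.415 to 9 TPM in the other lines. Cdh5 was at 140.5 ± 143.3 TPM and did not pass the test against eHB (2.43 ± 1.14, adjusted p = 0.0928). Hypoxia and glycolysis genes rose in 14 of 20 cases and fell in 1 (camera adjusted p = 3.72e-08, adjusted p = 0.0745 with an estimated correlation). Egln3, an oxygen-sensing enzyme, rose (5.10 ± 0.33, adjusted p = 1.13e-05) and Hk2 fell (-1.15 ± 0.34, adjusted p = 0.0154). The oxygen level is stated for the blood cultures alone, at 1.5%. Endogenous Mycn (4.82 ± 1.30, adjusted p = 0.0108) and Lmo2 (2.81 ± 0.76, adjusted p = 0.0108) rose, and Msi1, an RNA-binding protein of progenitor cells, was among the genes that fell most (-7.39 ± 0.69, adjusted p = 7.42e-05). Counts adjusted over the list alone were otherwise the same. Of 12269 genes tested, 3498 were higher and 3134 lower, the test against a 2-fold change left 1248 and 761, and limma on log2 TPM called 1673 and 5745.

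**Figure D2:**
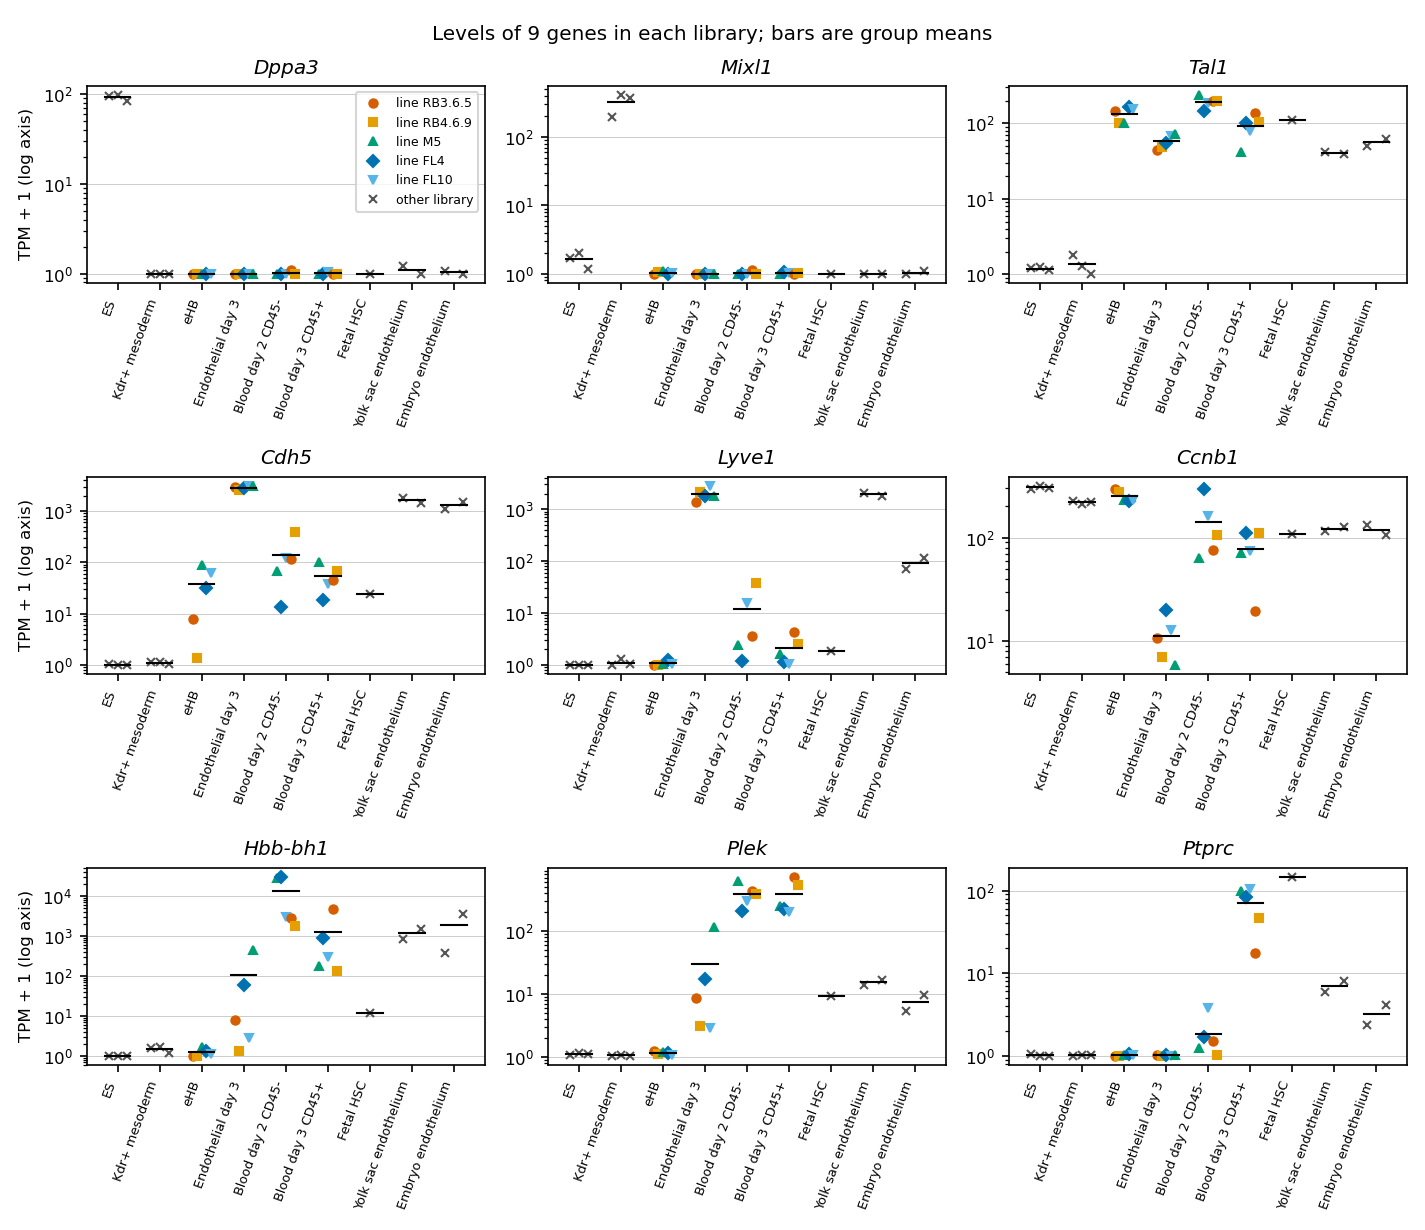
Levels of 9 genes in TPM + 1 on a log axis, with 1 symbol per library, the 5 eHB-derived lines marked by colour and shape, and a bar at each group mean. Cdh5 and Lyve1 are highest in the endothelial cultures (means 2890 and 1992 TPM), Hbb-bh1 in day 2 blood (13420 TPM), and among the cultures Ptprc in day 3 blood (68.8 TPM).

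Day 3 CD45-positive blood was compared with day 2 CD45-negative blood. Day and sort gate change together here, so their effects cannot be told apart. Below, rose and fell describe the day 3 cells as sorted against the day 2 cells as sorted. Myeloid, macrophage and pan-leukocyte genes were higher on day 3. Ptprc, whose product the gate selected on, was at 68.8 ± 36.8 TPM on day 3 and 0.851 ± 1.09 TPM on day 2 (6.27 ± 0.95, adjusted p = 0.00356, n = 5 and 5). Of the myeloid list 18 of 22 rose, 20 when adjusted over the list alone (camera adjusted p = 5.03e-23, adjusted p = 0.188 with an estimated correlation). The granule protein gene Ngp was at 112 ± 193.6 TPM on day 3 and 0.0122 ± 0.0273 TPM on day 2, and Camp averaged 49 TPM against 0.0818 ± 0.126 TPM. Of the leukocyte list 15 of 22 rose (camera adjusted p = 7.27e-15, adjusted p = 0.147 with an estimated correlation), including Cd53 (5.39 ± 0.94, adjusted p = 0.00666). Of the macrophage list 5 of 6 rose (camera adjusted p = 1.41e-08, adjusted p = 0.147 with an estimated correlation), including Emr1, the gene of F4/80 (7.35 ± 1.25, adjusted p = 0.00616). The stefin genes Stfa2l1 and Stfa3, encoding protease inhibitors, were at least 1480-fold and 983-fold higher. Line M5 alone held 469 TPM of Stfa2l1, 457 of Ngp and 223 of Camp, above the 19.7 to 85.8, 7.92 to 48.3 and 3.18 to 10.2 TPM of the other 4 lines. Igf2, an imprinted growth factor, fell (-1.77 ± 0.33, adjusted p = 0.00992), as did Smtnl2 (-3.53 ± 0.43, adjusted p = 0.00163).

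Camera also called the pan-endothelial list lower on day 3 with 2 of 21 members fallen (adjusted p = 0.000839, adjusted p = 0.601 with an estimated correlation) and the erythroid list with 1 of 20 (adjusted p = 0.000839, adjusted p = 0.601 with an estimated correlation). Line RB3.6.5 went the other way, its sum over 8 erythroid genes rising from 4810 TPM on day 2 to 17900 TPM on day 3, while the sum fell in the other 4 lines. It called the proliferation list with 0 of 20 (adjusted p = 0.0316, adjusted p = 0.694 with an estimated correlation), and the imprinted list with 2 of 14 fallen, 3 when adjusted over the list alone, and 1 risen (adjusted p = 0.0477, adjusted p = 0.597 with an estimated correlation). The other counts did not differ when adjusted over the list alone. The proliferation call ended without day 3 RB3.6.5 (adjusted p = 0.232) or day 2 FL4 (0.257) or FL10 (0.0717), and the imprinted call without day 3 M5 (0.0589) or FL4 (0.0657) or day 2 FL10 (0.0753) or RB4.6.9 (0.121). Of 12084 genes tested, 883 were higher and 347 lower, DESeq2 called 1520 and 1135, and glmTreat 336 and 12. A single fit of all 31 libraries called 1759 and 1915, and limma on log2 TPM 698 and 155. Without day 3 RB3.6.5, in which Lars2 took 10.3% of counts against 0.085% to 0.237% in the other 4, the counts were 1151 and 779, and without day 3 M5 554 and 103. Higher genes numbered 574 without day 3 FL10, and lower genes 123 without day 3 FL4, 107 without FL10 and 156 without RB4.6.9, and 209, 138 and 207 without day 2 FL4, RB3.6.5 and RB4.6.9.

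Day 3 blood was compared with the endothelial cultures of the same lines, which had equally spent 3 days outside doxycycline. Their media differed, and the oxygen level is stated for the blood cultures alone, at 1.5%. Cell type and culture conditions therefore cannot be told apart. Day 3 blood had higher levels of leukocyte genes and lower levels of endothelial genes. Of the leukocyte list 20 of 22 rose (camera adjusted p = 1.88e-12, adjusted p = 0.17 with an estimated correlation), with Ptprc (12.58 ± 0.77, adjusted p = 1.09e-06) and Dock2 (10.09 ± 0.75, adjusted p = 3.07e-06) leading. The blood gate selected on CD45, the product of Ptprc, so the rise of Ptprc only reflects the sort. Of the myeloid list 21 of 22 rose (camera adjusted p = 8.67e-11, adjusted p = 0.283 with an estimated correlation), including S100a9, a subunit of calprotectin (12.96 ± 1.83, adjusted p = 0.000168), at 15600 TPM in M5 and 270 to 1950 TPM in the other 4. Of the macrophage list 5 of 6 rose (camera adjusted p = 0.00377, adjusted p = 0.323 with an estimated correlation). The pan-endothelial list fell in 20 of 24 cases (camera adjusted p = 2.15e-09, adjusted p = 0.283 with an estimated correlation). The arterial list fell in 11 of 14 (camera adjusted p = 1.83e-05, adjusted p = 0.237 with an estimated correlation) and the venous and lymphatic list in 8 of 10 (camera adjusted p = 0.00413, adjusted p = 0.323 with an estimated correlation). Cdh5 was lower (-5.35 ± 0.46, adjusted p = 7.87e-06) though both populations express it, and Lyve1 (-10.36 ± 1.21, adjusted p = 5.01e-05), Dll4 (-7.96 ± 1.52, adjusted p = 0.00113) and Robo4 (-7.99 ± 1.33, adjusted p = 0.000486) fell further.

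Proliferation genes were higher in day 3 blood than in the endothelial cultures in 19 of 20 cases (camera adjusted p = 5.38e-06, adjusted p = 0.443 with an estimated correlation), such as Aurkb (3.39 ± 0.48, adjusted p = 0.000168). Hypoxia and glycolysis genes rose in 15 of 21 cases and fell in 3 (camera adjusted p = 1.19e-07, adjusted p = 0.17 with an estimated correlation). Hk2, the first enzyme of glycolysis, rose (5.77 ± 0.47, adjusted p = 5.11e-06), and Adm, a vasodilator peptide made by endothelium, fell (-5.38 ± 1.69, adjusted p = 0.0181). Notch targets fell in 4 of 5 cases (camera adjusted p = 0.000472, adjusted p = 0.17 with an estimated correlation), including Hey1 (-9.49 ± 0.79, adjusted p = 5.89e-06), and FGF and ERK targets fell in 11 of 18 and rose in 1 (camera adjusted p = 0.00214, adjusted p = 0.283 with an estimated correlation). The endothelial medium contained FGF2 and the blood medium did not, and the effect of neither medium nor oxygen was tested. All 10 tested Hox genes fell (camera adjusted p = 0.00176, adjusted p = 0.402 with an estimated correlation), with Hoxb5 from 49.0 ± 24.5 to 0.0368 ± 0.0525 TPM. Imprinted genes fell in 10 of 14 cases and rose in 1 (camera adjusted p = 0.031, adjusted p = 0.273 with an estimated correlation), with Peg3 lower (-7.18 on the log2 scale, adjusted p = 0.000483). Adjusted over the list alone, 12 arterial genes fell and 1 rose, 1 Notch target rose, and the other counts stayed equal. Plac8 was at least 10900-fold higher and Nnmt at least 868-fold lower. Of 12655 genes tested, 3932 were higher and 3826 lower, against 1812 and 1840 in the test against a 2-fold change and 2362 and 5000 by limma on log2 TPM.

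The endothelial cultures were then set against primary endothelium of yolk sac and embryo pooled as 1 group (n = 5 and 4). The sorting markers Cdh5 and Pecam1 were higher in culture and Kdr did not pass the test, whereas genes of other cell types and of the cell cycle were lower. Kdr was at 685 ± 102 TPM in culture and 828 ± 256 TPM in primary cells (adjusted p = 0.285). Endogenous Tal1 (56.7 ± 12.3 and 47.3 ± 10.2 TPM, adjusted p = 0.216), Sox17 (175 ± 119 and 162 ± 25.1 TPM, adjusted p = 0.778) and Mycn (40.6 ± 12.8 and 40.1 ± 17.4 TPM, adjusted p = 0.993) did not pass the test either. Cdh5 was higher in culture (1.00 ± 0.14, adjusted p = 0.00046), as was Pecam1 (0.76 ± 0.15, adjusted p = 0.00302). The pan-endothelial, arterial and venous and lymphatic lists were not called. The proliferation list fell in 19 of 20 cases (camera adjusted p = 2.29e-18, adjusted p = 0.294 with an estimated correlation), with Ccnb2 at 9.79 ± 5.19 TPM in culture and 140 ± 3.87 TPM in primary cells (-3.86 ± 0.36, adjusted p = 6.39e-05). BMP targets fell in 8 of 9 cases (camera adjusted p = 0.00251, adjusted p = 0.294 with an estimated correlation), including Smad7 (-3.72 ± 0.45, adjusted p = 0.000193). The culture medium contained both BMP4 and the TGF-beta receptor inhibitor SB431542, and the effect of neither was tested. FGF and ERK targets rose in 10 of 18 cases and fell in 1 (camera adjusted p = 0.00585, adjusted p = 0.294 with an estimated correlation), led by Spred3 (3.17 ± 0.18, adjusted p = 8.98e-06), and Il17rd fell (-2.20 ± 0.35, adjusted p = 0.00086).

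Markers of macrophages (11 of 12 fell, camera adjusted p = 2.29e-18, adjusted p = 0.143 with an estimated correlation), fibroblasts and matrix (13 of 14, camera adjusted p = 4.78e-06, adjusted p = 0.294 with an estimated correlation) and smooth muscle (8 of 12, camera adjusted p = 0.0295, adjusted p = 0.382 with an estimated correlation) were lower in culture than in primary endothelium. C1qb, a complement gene of tissue macrophages, was at 97.2 ± 32.03 TPM in the primary libraries and at least 2710-fold lower in culture, and Col1a2 fell (-11.82 ± 1.84, adjusted p = 0.000719). The leukocyte list fell in 12 of 22 cases and rose in 2 (camera adjusted p = 0.000314, adjusted p = 0.473 with an estimated correlation). The myeloid list fell in 10 of 15 and rose in 2 (camera adjusted p = 0.00585, adjusted p = 0.473 with an estimated correlation), and the lymphoid list fell in 3 of 4 (camera adjusted p = 0.00936, adjusted p = 0.294 with an estimated correlation). The erythroid list fell in 5 of 20 cases (camera adjusted p = 0.0377, adjusted p = 0.778 with an estimated correlation), with Slc4a1, the red cell anion exchanger, lower (-6.49 ± 1.39, adjusted p = 0.00394). Summed after their values were seen, globin and erythroid transcripts differed widely within both groups. They reached 2700 to 33900 TPM in the primary libraries, and 2280 TPM in the M5 culture against 3.01 to 156 TPM in the other cultures. The lateral mesoderm list fell in 9 of 14 cases and rose in 1 (camera adjusted p = 0.00704, adjusted p = 0.294 with an estimated correlation), with Foxf1 lower (-9.75 ± 1.33, adjusted p = 0.000366). The pluripotency list fell in 5 of 6 cases (camera adjusted p = 0.00251, adjusted p = 0.143 with an estimated correlation), led by Klf2 (-5.05 ± 0.37, adjusted p = 2.69e-05), which is also a flow-responsive gene of endothelium. Adjusted over the list alone, 20 proliferation, 13 leukocyte, 11 myeloid and 4 erythroid genes fell and 3 myeloid genes rose, with the other counts equal. Higher in culture were Serpinb11 (11.87 ± 0.51, adjusted p = 4.27e-06) and Psg22 (11.09 ± 1.29, adjusted p = 0.000165). Afp, made by visceral endoderm, fell (-13.82 ± 2.60, adjusted p = 0.00197) from a primary mean of 3697 TPM, which averages 7389 TPM in yolk sac with 4.59 TPM in embryo endothelium. Of 13256 genes tested, 3374 were higher and 3528 lower, and the test against a 2-fold change left 798 and 1481.

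Yolk sac endothelium was compared with embryo endothelium at the same embryonic day (n = 2 and 2). Genes of hepatic and visceral endoderm type and of connective tissue were far higher in the yolk sac libraries. Of the hepatic and visceral endoderm list 15 of 16 rose, and 16 when adjusted over the list alone (camera adjusted p = 1.6e-64, adjusted p = 0.275 with an estimated correlation). Afp was at 7389 ± 5.07 TPM in yolk sac and 4.59 ± 2.49 TPM in embryo (10.54 ± 0.60, adjusted p = 1.51e-06) and Apoa4 at 461.9 ± 19.04 and 0.202 ± 0.227 TPM (11.27 ± 0.44, adjusted p = 2.16e-07). Of the fibroblast and matrix list 11 of 15 rose and 2 fell (camera adjusted p = 2.03e-13, adjusted p = 0.426 with an estimated correlation), with Col1a1 higher (7.32 ± 0.32, adjusted p = 4.04e-07) and Thy1 lower (-2.41 ± 0.38, adjusted p = 0.00113). All 13 interferon response genes tested rose (camera adjusted p = 1.55e-07, adjusted p = 0.662 with an estimated correlation), including Ifit3 (4.06 ± 0.51, adjusted p = 0.000275). Smooth muscle genes rose in 8 of 12 cases and fell in 1 (camera adjusted p = 0.00287, adjusted p = 0.426 with an estimated correlation). The megakaryocyte list rose in 8 of 15 and fell in 1 (camera adjusted p = 0.00287, adjusted p = 0.426 with an estimated correlation), and the leukocyte list rose in 13 of 22 and fell in 2 (camera adjusted p = 0.00576, adjusted p = 0.858 with an estimated correlation). Acta2 (4.48 ± 0.23, adjusted p = 1.03e-06), Itga2b (2.71 ± 0.28, adjusted p = 6.99e-05) and Cd44 (2.67 ± 0.22, adjusted p = 1.49e-05) led these lists.

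Wnt targets were lower in yolk sac in 7 of 10 cases (camera adjusted p = 2.32e-06, adjusted p = 0.426 with an estimated correlation). Lef1, a nuclear effector of the Wnt pathway, was at 0.287 ± 0.274 TPM against 21.5 ± 1.58 TPM (-6.53 ± 0.44, adjusted p = 4.76e-06), and Apcdd1 fell as well (-3.57 ± 0.27, adjusted p = 9.03e-06). The neural list fell in 6 of 8 cases (camera adjusted p = 0.00398, adjusted p = 0.426 with an estimated correlation), with Zic1 at least 27.7-fold lower. Camera called the cardiac list lower with 6 of 10 fallen (adjusted p = 0.0217, adjusted p = 0.449 with an estimated correlation). It called the lymphoid list lower with 3 of 4 fallen (adjusted p = 0.0217, adjusted p = 0.449 with an estimated correlation) and the imprinted list higher with 6 of 14 risen and 1 fallen (adjusted p = 0.0217, adjusted p = 0.662 with an estimated correlation). The cardiac call ended without embryo library 1 (adjusted p = 0.0523), the lymphoid call without yolk sac library 1 (0.12) or embryo library 1 (0.0707), and the imprinted call without embryo library 1 (0.066) or 2 (0.0523). Adjusted over the list alone, 11 megakaryocyte, 14 leukocyte and 1 cardiac gene rose, 2 smooth muscle and 2 imprinted genes fell, and the other counts were equal. The calcium-binding protein gene S100g was at least 1300-fold higher in yolk sac, and the chemokine gene Ccl21a at least 222-fold lower. Endogenous Lmo2 was lower in yolk sac (-1.57 ± 0.19, adjusted p = 0.000214). Of 13673 genes tested, 2175 were higher and 1168 lower. The test against a 2-fold change left 1056 and 318, and a single fit of all 31 libraries 468 and 122. Leaving out yolk sac library 1 gave 716 lower genes, yolk sac library 2 737 and embryo library 2 1860.

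The eHB lines from tissue (M5, FL4, FL10) were compared with those from ES cells (RB3.6.5, RB4.6.9). The labels tie origin to medium: the ES-derived lines also received VEGF, BMP4, a cyclic AMP analogue and the TGF-beta receptor inhibitor SB431542, and the tissue-derived lines did not. BMP target transcripts and those of the Hoxb cluster were lower in the tissue-derived lines. Of the BMP target list 5 of 9 fell, 7 when adjusted over the list alone (camera adjusted p = 3.38e-06, adjusted p = 0.515 with an estimated correlation). Id3 was at 0.200 ± 0.129 TPM in tissue-derived and 136.7 ± 34.99 TPM in ES-derived lines (-9.36 ± 0.45, adjusted p = 0.0175, n = 3 and 2), and Smad6 fell too (-7.09 ± 0.33, adjusted p = 0.0175). Of the Hox list 4 of 11 fell, 6 when adjusted over the list alone (camera adjusted p = 0.00268, adjusted p = 0.515 with an estimated correlation). Hoxb2 was at 0.0177 ± 0.0306 and 43.97 ± 16.04 TPM, and Hoxb5 at least 76.2-fold lower. All 7 tested Hoxb genes lay below 0, while the 4 tested Hoxd genes lay at 0.099 to 0.718 and none of these passed. Imprinted genes fell in 4 of 14 cases and rose in 1 (camera adjusted p = 0.0377, adjusted p = 0.515 with an estimated correlation), including Mest (-4.65 ± 0.91, adjusted p = 0.0424). The lateral mesoderm list was called lower with 1 of 10 fallen (camera adjusted p = 0.0303, adjusted p = 0.515 with an estimated correlation). The hemogenic factor list was called higher with 1 of 16 risen, 2 when adjusted over the list alone, and 1 fallen (camera adjusted p = 0.0389, adjusted p = 0.951 with an estimated correlation), with Runx1 higher (3.49 ± 0.46, adjusted p = 0.0277). The pan-endothelial list was called higher with 0 of 18 members past the test (camera adjusted p = 0.0303, adjusted p = 0.951 with an estimated correlation) and the erythroid list with 1 of 13 (camera adjusted p = 0.0377, adjusted p = 0.951 with an estimated correlation). The remaining counts did not differ when adjusted over the list alone. Without RB4.6.9 the calls of 5 lists ended: hemogenic (adjusted p = 0.808), pan-endothelial (0.852), erythroid (0.23), imprinted (0.0894) and lateral mesoderm (0.0844). Without RB3.6.5 the imprinted (0.068) and lateral mesoderm (0.0852) calls ended, and the hemogenic and erythroid calls ended without M5 (0.136 and 0.113) or FL4 (0.0757 and 0.0736). Outside the lists, Pdlim4 was at least 717-fold lower and the imprinted gene Peg12 higher (4.18 ± 0.24, adjusted p = 0.0207). Of 12759 genes tested, 582 were higher and 919 lower, but without any 1 of the 5 lines at most 8 and 21 passed, DESeq2 called 1919 and 2107 and glmTreat 4 and 12.

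After 3 days in one shared endothelial medium, 1 gene differed by origin between the same lines. Arhgef5, a guanine nucleotide exchange factor, was at 0.989 ± 0.122 TPM in tissue-derived and 51.2 ± 12.3 TPM in ES-derived cultures (-5.68 ± 0.21, adjusted p = 0.0169), and it did not pass without any 1 of the 5 libraries (adjusted p = 0.0842 to 0.296). The edgeR test called 0 genes higher and 1 lower of 12860, with 1166 and 1198 at an unadjusted p under 0.05, DESeq2 called 775 and 831, limma on log2 TPM 4 and 12, and a single fit of all 31 libraries 40 and 55. A test of the difference between the stages (interaction) called 0 of 13761 genes with edgeR, with 2177 at an unadjusted p under 0.05. With the line as a block, which takes account of the shared lines, it called 1 gene, Dlk1 (interaction 7.28, adjusted p = 0.0165), with 2421 at an unadjusted p under 0.05. No other tool was run on the interaction. As a list, Hox genes were lower in tissue-derived endothelial cultures, with 0 of 15 called singly and 8 lower when adjusted over the list alone (camera adjusted p = 2.25e-07, adjusted p = 0.564 with an estimated correlation). Leukocyte genes (0 of 17, 1 higher over the list alone, camera adjusted p = 0.000743, adjusted p = 0.901 with an estimated correlation), megakaryocyte genes (0 of 13, 2 higher over the list alone, camera adjusted p = 0.00467, adjusted p = 0.901 with an estimated correlation) and erythroid genes (0 of 18, camera adjusted p = 0.00689, adjusted p = 0.901 with an estimated correlation) were called higher as lists. The erythroid call ended without M5 (adjusted p = 0.422), and all 3 ended without RB4.6.9 (adjusted p = 0.0803 for leukocyte, 0.0658 for megakaryocyte and 0.0803 for erythroid genes).

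**Figure D3:**
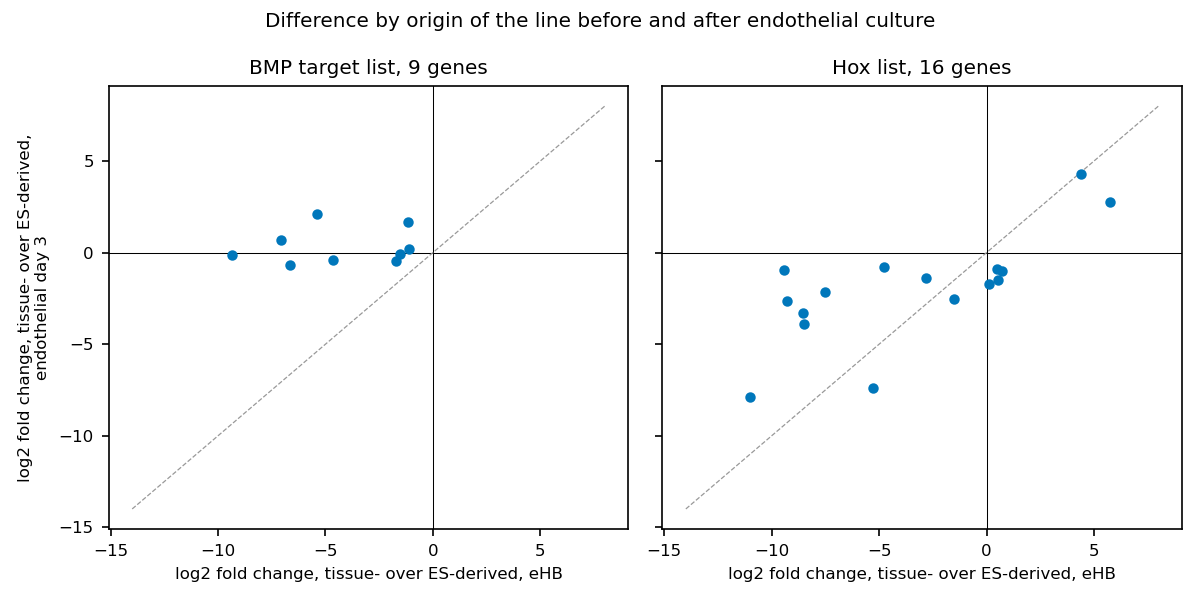
Log2 fold change of tissue-derived over ES-derived lines in the eHB state (x axis) and in the endothelial cultures (y axis) for the members of the BMP target and Hox lists, 1 point per gene, with a dashed line of equal change. BMP targets lie left of 0 in eHB and spread around 0 in the endothelial cultures (list medians -4.66 and -0.09), while most Hox genes lie below 0 on both axes and 2 above 0 on both (medians -3.80 and -1.62 over 16 genes).

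The single HSC library was compared with day 3 blood by values alone, and no test was run. HSCs were higher in stem and progenitor genes and lower in myeloid genes than day 3 blood. Hlf was at 256 TPM in HSCs and at most 0.604 TPM in the 5 blood libraries, Mecom at 154 and at most 0.449 TPM, and Hoxa9 at 139 TPM and at 0 in all 5. S100a9 and S100a8 were at 0 in HSCs and at 270 to 15600 and 182 to 8080 TPM in blood, and Cdkn2a, the gene of the cell cycle inhibitors p16 and p19, at 0 and 217 to 770 TPM. Of the stem and progenitor list 20 of 21 members were above all 5 blood libraries, and the list's median difference of log2(TPM + 1) was 3.48, at percentile 100 among 10000 random lists of matched expression. The median was 3.63 for Hox genes (percentile 100, 6.65 with a pseudocount of 0.1), 1.197 for proliferation genes (percentile 100), -3.69 for myeloid genes (percentile 0) and -1.11 for hypoxia and glycolysis genes (percentile 0). A median of 0 is not the baseline, since lists near the middle of the random lists lay above it. The hepatic and visceral endoderm list had 0.885 (percentile 53.8) and Notch targets had 0.584 (percentile 40.4). Ptprc was at 145 TPM in HSCs and 16.4 to 102 TPM in day 3 blood. The HSC library also held 1660 TPM of Hbb-bt.

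Each culture was finally compared with the mean of each control group by Spearman correlation across 14786 genes, which are not independent replicates. All 5 eHB lines were closest to Kdr-positive mesoderm (mean correlation 0.883 ± 0.006 SD), ahead of embryo endothelium (0.823 ± 0.010). All 5 endothelial cultures were closest to embryo endothelium (0.878 ± 0.013), followed by yolk sac endothelium (0.846 ± 0.010), and all 5 day 3 blood cultures to HSCs (0.862 ± 0.035). Day 2 blood was closest to HSCs in 4 of 5 lines (0.850 ± 0.024) and to embryo endothelium in 1 (mean 0.838 ± 0.036). The HSC library was the only control of blood cells, so the ranking does not show a likeness to HSCs over other blood cells. Mean correlations with embryo endothelium also exceeded those with yolk sac endothelium for eHB (0.823 and 0.76), day 2 blood (0.838 and 0.808) and day 3 blood (0.793 and 0.771). The order of these controls is therefore not particular to the endothelial cultures. The control groups correlated with each other at 0.669 to 0.936.

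**Figure D4:**
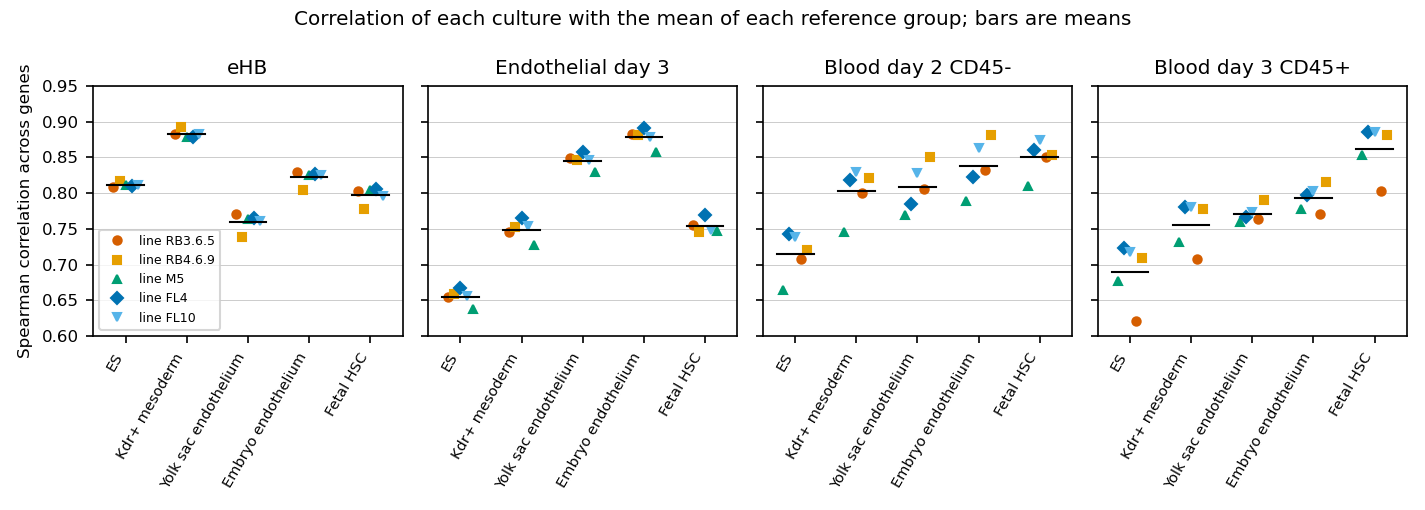
Spearman correlation of each culture with the mean profile of 5 control groups, 1 symbol per line and a bar at the mean, for eHB, endothelial, day 2 blood and day 3 blood cultures. The highest mean lies at mesoderm for eHB (0.883), embryo endothelium for endothelial cultures (0.878) and HSCs for both blood stages (0.850 and 0.862).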

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

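The tests of BMP targets, Hox genes, the Gata2 rows and the scaling were chosen after the result was seen; those of Tal1 and the epithelial list were not. In 160 sets of 4 to 10 values, 1 library lay beyond Dixon's limit (0.71 of the range for 5 libraries) in 23. About 1 in 20 sets exceeds it by chance if the values are independent and normally distributed. TPM values need not be, and genes can vary together, so the rate expected here is not known. The TPM values that follow are 1 library against the range of the other 4 lines of its group.

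In eHB, FL4 held 83.5 TPM of Pkd2l1 (others 0.419 to 16.2), RB3.6.5 held 43 TPM of Sox7 (others 0.116 to 10.7), and RB4.6.9 held 0.959 TPM of Tie1 (others 102 to 121). In endothelial cultures, RB3.6.5 held 645 TPM of Cxcr4 (others 144 to 276), FL10 held 146 TPM of ectopic Lmo2 (others 5.83 to 37.6), and M5 held 21.3 TPM of ectopic Mycn (others 3.96 to 7.8). In day 2 blood, FL4 held 127 TPM of ectopic Tal1 (others 1.49 to 33.8). M5 held 198 TPM of Fyb (others 8.07 to 49.6), 3530 TPM of Hbb-bt (others 132 to 507) and 635 TPM of Treml1 (others 35.3 to 153). RB4.6.9 held 32.1 TPM of Robo4 (others 0.415 to 9) and 95.9 TPM of Sox18 (others 1.98 to 29).

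In day 3 blood, Lars2 took 10.3% of the counts of RB3.6.5 (others 0.085% to 0.237%), and its 10 most abundant genes took 17.5% (others 5.98% to 6.71%). Line M5 was highest in 9 genes: Bnip3 at 239 TPM (others 165 to 182), Camp at 223 (3.18 to 10.2), Ccr1 at 69 (11.6 to 16.9), Cd14 at 22.4 (1.51 to 7.37), Cd53 at 68.8 (6.36 to 14.3), Ngp at 457 (7.92 to 48.3), S100a9 at 15600 (270 to 1950), Stfa2l1 at 469 (19.7 to 85.8) and Stfa3 at 276 (27.5 to 60.9). These values come from 1 culture, and no explanation was tested.

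The effect of origin differed between the eHB state and the endothelial cultures for 2 of 32 lists in a test of the difference itself. The pan-endothelial list moved by a median of -1.36 on the log2 scale (0.96 in eHB, -0.06 in endothelial cultures, interaction camera adjusted p = 8.29e-05), and BMP targets moved by 4.25 (adjusted p = 2.74e-09). Neither call held with an estimated correlation (adjusted p = 0.524 and 0.211). Adjusted fry values were 0.242 and 0.028, and fry also called the imprinted (0.0245) and cyclic AMP target (0.0349) lists. That fit leaves out that both stages come from the same lines. With the line as a block the medians were -1.69 and 4.14 (camera adjusted p = 0.00342 and 7.41e-05), no list held with an estimated correlation, and fry called the imprinted list alone (0.0132; BMP targets 0.0759).

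The first pattern weighed is the lower level of BMP targets and of the Hox list, through its Hoxb genes, in the tissue-derived eHB lines. In the endothelial cultures, whose medium was the same for all lines, the BMP target median was -0.09, against -4.66 in eHB. A candidate explanation is therefore the medium at harvest, since BMP4 was given to the ES-derived lines alone, though the difference between the stages rests on the preset correlation. The Hox median was -1.52 in the endothelial cultures (-1.62 in the fit with the interaction, where it was -3.80 in eHB), which argues against the medium at harvest as the whole cause for Hox genes, though the camera call did not hold with an estimated correlation (adjusted p = 0.564). The Hox difference between the stages was not called (median 0.69, interaction camera adjusted p = 0.164). The origin of the cells and earlier medium stay open, untested, for both lists. With Hox genes absent from a group set to their floor, the medians of the interaction fit did not change. In the fit of eHB lines alone, with 11 Hox genes of which 3 were absent from a group, the median moved from -7.54 to -5.38.

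The second pattern is the high level of the endogenous Gata2 and Tal1 transcripts in eHB, which share coding sequence with the ectopic ones. Endogenous Gata2 varied 1.73-fold over the 5 lines while ectopic Gata2 varied 102-fold, which argues against shared reads as the whole source of the Gata2 level. Endogenous Tal1 varied 1.64-fold and ectopic Tal1 3.27-fold, a range too narrow to decide, so for Tal1 shared reads and endogenous transcription cannot be told apart. No other biological explanation was tested.

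The third pattern is the high level of hepatic and visceral endoderm genes in yolk sac endothelium. The epithelial list of 12 genes had 11 tested members, all higher in yolk sac, with a median log2 fold change of 6.32, and Krt8 and Krt18 were at 223 and 214 TPM against 1.25 and 2.62 TPM. Embryo endothelium held 0.036 to 6.6 TPM of the 11 genes. Endoderm cells or their RNA in the sorted libraries may therefore contribute, although the sort took VE-cadherin and Pecam1 positive cells. Scaling shifted by a few abundant genes is argued against, since a scaling factor moves all genes of a library alike, and the hepatic and visceral endoderm median lay 8.34 above the median of all genes tested. Transcription of these genes in yolk sac endothelium itself was not tested.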

How the results depend on the processing

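The removal of the ectopic transcripts, globins and Lars2 and the block and estimated correlation for the interaction were chosen after the result was seen; the other alternatives and the regroupings of libraries were not. Counts are given as higher and lower genes. With that removal, with DESeq2 size factors and with no filter on low counts, every count stayed within 1.5 times its reported value. Where a count moved further, the cause was not tested, except that glmTreat asks for a change beyond 2-fold.

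glmTreat left 2253 and 2781 genes for mesoderm against ES cells, 827 and 1087 for eHB against mesoderm, and 2203 and 2114 for endothelial cultures against eHB. It left 1248 and 761 for day 2 blood against eHB, 336 and 12 for day 3 against day 2 blood, 1812 and 1840 for day 3 blood against endothelial cultures, 798 and 1481 for endothelial cultures against primary endothelium, 1056 and 318 for yolk sac against embryo, and 4 and 12 for origin in eHB. The fit of all 31 libraries gave 3589 lower in mesoderm, 4793 lower in day 2 blood against eHB, 1759 and 1915 for day 3 against day 2 blood, 468 and 122 for yolk sac against embryo, and 40 and 55 for origin in endothelial cultures. Limma on log2 TPM gave 1695 lower for eHB against mesoderm, 1673 and 5745 for day 2 blood against eHB, 155 lower for day 3 against day 2 blood, 2362 higher for day 3 blood against endothelial cultures, and 4 and 12 for origin in endothelial cultures. The DESeq2 Wald test gave 1520 and 1135 for day 3 against day 2 blood, 1919 and 2107 for origin in eHB, and 775 and 831 for origin in endothelial cultures. Fetal liver lines alone gave 8 and 21 for origin in eHB and 0 lower in endothelial cultures. With an estimated correlation 8 of 82 list calls held. Limma shifted the median log2 fold change of all genes by -0.325, 0.287, -0.657, 0.106 and -0.396 (mesoderm, eHB, day 2 blood, day 3 against day 2 blood, day 3 blood against endothelial cultures), and the fit of all libraries by 0.11 and -0.119 (mesoderm, day 2 blood).

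Leaving out 1 library at a time gave 4975 to 5520 higher and 5103 to 5713 lower genes in mesoderm, 2118 to 3186 and 2332 to 3172 for eHB against mesoderm, 4138 to 4314 and 4303 to 4481 for endothelial cultures against eHB. The ranges were 3165 to 3516 and 2632 to 3256 for day 2 blood, 554 to 1151 and 103 to 779 for day 3 against day 2 blood, 3693 to 4318 and 3530 to 4320 for day 3 blood against endothelial cultures. They were 2994 to 3263 and 3172 to 3487 against primary endothelium, 1675 to 2389 and 716 to 1860 for yolk sac, 0 to 8 and 0 to 21 for origin in eHB, and 0 and 0 for origin in endothelial cultures. List calls numbered 80 to 93, and HSCs had 2078 to 2682 genes above and 513 to 560 below day 3 blood (2513 and 527 with all libraries). Where 1 library was left in a group, it was assumed to vary like the others. Over these refits, calls of named genes were lost in 168 cases, gained in 3 and unaltered in 2095, and list calls were lost in 32 cases and held in 677. Calls of named genes were also lost under the fit of all libraries (38, with 3 gained), glmTreat (44), limma (10), no filter (7) and fetal liver lines alone (14).

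Among genes that did not pass against primary endothelium, 4 changed sign. Kdr did with embryo endothelium alone (0.02) and Lmo2 with yolk sac alone (0.27). Mycn did with DESeq2 size factors (-0.01), the Wald test (0) and embryo alone (-0.45) and without endothelial RB3.6.5 (-0.13) or FL4 (-0.09) or yolk sac 1 (-0.16) or 2 (-0.17). Sox17 did by limma (-0.17) and without RB3.6.5 (-0.19) or FL4 (-0.02). With 1 library left out, Mycn ranged up to 0.21 and Sox17 up to 0.4.

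With the line as a replicate block the counts were 5177 and 5348 for mesoderm, 4601 and 4680 for endothelial cultures against eHB, 3374 and 3156 for day 2 blood, 946 and 386 for day 3 against day 2 blood, and 3756 and 3847 for day 3 blood against endothelial cultures. Of 151 genes, 5 lost and 1 gained the call, of 40 lists the venous and lymphatic list in endothelial cultures lost it (adjusted p = 0.082), and no other call of these changed. The block gave 1 gene in place of 0 for the interaction of origin and stage. Yolk sac and embryo libraries share only a number (correlation of deviations -0.068), and that block gave 2011 and 963.

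Other splits of the same libraries were fitted to ask whether chance gives as many genes. For mesoderm against ES cells the 10 splits are too few for a share under 0.05 (real 10716, highest other 0). In the other 6, only 1 split reached the real count, the real one. For eHB against mesoderm (6186 against 569 at most, 56 splits) and for primary endothelium (6902 against 3211, 80 splits) the share was under 0.05. A share of this size does not exclude chance. It also takes the libraries as independent and alike within a group. The labels do not state independence for yolk sac and embryo, and the eHB lines differ in origin and medium. In the 4 comparisons paired by line, with 80 splits each, the counts were 8803 against 0 for endothelial cultures against eHB, 6632 against 1 for day 2 blood, 1230 against 754 for day 3 against day 2 blood, and 7758 against 0 for day 3 blood against endothelial cultures. The splits that part every line, as the real one does, numbered 11, 12, 10 and 8, too few for a share under 0.05, with 0 as the highest other. The splits with calls keep some lines together.

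With a pseudocount of 0.1, 7 list medians of HSCs against day 3 blood moved by more than the spread between blood libraries and 10 did not, none with a change of sign. The stem and progenitor median became 4.42 and the Hox median 6.65. Over refits without 1 blood library such medians moved in 15 cases, none with a change of sign, and the Hox median stayed at 3.62 to 3.64.

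Among single libraries, depth limits low genes most in day 3 blood of RB3.6.5, which held 9424412 counts.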

Other observations

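The values here, including the tests of origin in blood cultures, were chosen after the result was seen, except the HSC lists. Apart from those tests of origin, no hypothesis was tested on the values.

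Transcripts of the Y chromosome summed to 0.136 TPM in eHB line RB3.6.5, 0.021 in M5 and 0.074 in FL4, against 115 in RB4.6.9 and 83.6 in FL10. In ES cells and mesoderm they summed to 75.4 and 18.7 TPM for RB2, 66 and 20.2 TPM for RB3, and 101 and 29.6 TPM for RB4. The sum over erythroid genes was 65500 TPM in day 2 blood of M5 and 61400 in that of FL4, against 3240 to 6370 in the other 3 cultures. In day 3 blood it was 17900 TPM in RB3.6.5 against 1040 to 2890 in the other 4, and in endothelial cultures 2280 TPM in M5 against 3.01 to 156. It was 2250 TPM in HSCs, 6000 and 12300 in the yolk sac libraries, and 2700 and 33900 in the embryo endothelium libraries. By origin, edgeR called 0 genes in day 2 blood (500 at an unadjusted p under 0.05) and 0 in day 3 blood (1540), and no other tool was run on these.

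In the HSC library, the median difference of log2(TPM + 1) from day 3 blood was 1.951 for the pan-endothelial list (percentile 100), 1.888 for the interferon list (percentile 99.8), -3.142 for the megakaryocyte list (percentile 0) and -2.999 for the mast cell and basophil list (percentile 0). Of the pan-endothelial list, Kdr was lower at 5.77 TPM against a mean of 21.7 TPM in blood, Cdh5 at 23.6 against 53.4 TPM and Pecam1 at 80.4 against 172 TPM, and only Pecam1 of these 3 lay below all 5 blood libraries.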
